A study of Drosophila melanogaster with 12 samples.

How the data were processed

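RNA was sequenced from cells sorted by FACS from dissociated brains of Drosophila larvae early in instar 3, in 4 groups of 3 libraries: GFP-positive and GFP-negative cells of wild-type (WT) brains and of rfx knock-out (KO) brains. GFP marks the cells that express Rfx. Per the labels, libraries were made from 4 ng of total RNA with the SMARTer Ultra Low and Nextera protocols, which keep no strand, and were sequenced on lanes 6 and 7. Replicate numbers follow the order of deposition, and replicates 1, 2 and 3 hold title numbers 13 to 16, 1 to 4 and 5 to 8. Title numbers 1 to 4 were on lane 6 and 13 to 16 on lane 7. Of title numbers 5 to 8, the WT libraries were on lane 6 and the KO libraries on lane 7. Lane is therefore partly confounded with genotype. Beyond the lane, the labels do not say what the libraries of a run of numbers share. The labels do not say that the replicates came from separate animals or dissections, so p-values measure the spread between libraries.

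The deposited table holds 12610 genes in 12 libraries and is named as normalised counts. The submitters' notes name TopHat2 2.0.13, HTSeq 0.6.1, edgeR 3.10.5 and the genome build BDGP6, without the role or order of each. The deposited signal of each library is a whole multiple of a single value, within a tolerance of 0.001, for 100% of values, so the values are gene read counts divided by an effective library size on the CPM scale. Whole reads were recovered from this, between 20301256 and 29771321 per library. Deposited column totals ran from 807057 to 1264329, so the effective library sizes carry scaling factors of the kind that TMM gives. The totals were 1020350 to 1264329 in GFP-positive and 807057 to 968551 in GFP-negative libraries. The scaling thus differs between the groups of the GFP comparisons, and their balance of higher and lower genes depends on it. The rule that chose the 12610 genes is not stated. The table holds 9 genes annotated as rRNA and 0 mitochondrially encoded genes.

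Gene names and positions came from a BDGP6.54 annotation, which is on the same assembly as the build in the labels, and 12389 of the 12610 identifiers were found in it. The other 221 identifiers were tested and counted without a name.

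Genes with a deposited value of at least 1 in at least 3 of the 12 libraries were tested, 9912 in all. The test was limma-trend (limma 3.58.1, R 4.3.3) on log2 of the value plus 1. One fit held all 12 libraries with group means, it was two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A floor of 10 had been set for counts and a floor of 1 for CPM; the values are on the CPM scale, so the floor of 1 was used. The comparisons were KO GFP-positive against WT GFP-positive, WT GFP-positive against WT GFP-negative, KO GFP-negative against WT GFP-negative, KO GFP-positive against KO GFP-negative, and the interaction of genotype with GFP, which tests whether the knock-out difference differs between the sorted populations. Exact permutation of 3 against 3 libraries cannot give a p under 0.1, so single genes rest on the limma fit.

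Named genes followed a rule written before the data were examined, as were the gene lists, the tests and most alternatives. Rfx is always named. For the first 2 comparisons the rule takes the 12 genes with the largest fold change in each direction, and for the other 3 comparisons the 4 largest, among called genes whose groups do not overlap and whose higher group has a mean of at least 5. From each list, up to 4 members with the smallest p are eligible. BBS1, CR41504, Oseg5, Dr, Ten-m, NetB, E2f1, brat, elav, ple, pros and rempA fall outside the rule and were named after their values were seen. A fold is the ratio of group means, and folds of the genes named for their size are also given without a library whose removal moves them by over 1.5 times.

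Of 31 gene lists, 29 had at least 3 tested members: intraflagellar transport, BBSome and ciliary base, axonemal dynein and ciliary motility, ciliated mechanosensory neurons, pan-neuronal genes, neuroblasts and progenitors, cell cycle, newborn neurons and Notch targets, glia, optic lobe and eye disc, mushroom body, hemocytes, fat body, muscle, trachea and epidermis, neurotransmitter synthesis and transport, neuropeptides and neurosecretory machinery, neurotransmitter receptors, voltage-gated and leak ion channels, synaptic vesicle and active zone, homeodomain and POU transcription factors, temporal patterning, ecdysone response, the cell recognition immunoglobulin family, axon guidance, heat shock and cell stress, immediate early genes, antimicrobial and immune response, and cytosolic ribosomal proteins. Some genes are members of more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation. Fry, which tests whether a list moves one way on balance and does not compare it with other genes, was run beside it. Every list called by camera kept the sign of its median under quantile normalisation, edgeR and DESeq2.

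Calls of the genotype comparisons were counted on chromosome 3 and on each arm against tested genes with a position, with Fisher's exact test, two-sided. Fold changes of comparisons that share no library were correlated across genes, which are not independent replicates, so no p is given. Their errors are not independent either, since libraries with adjacent title numbers correlate (below), so the correlation of the knock-out comparisons was set beside the other 9 splits of the 6 adjacent pairs into 3 and 3, a test added after seeing the data.

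Alternatives were a pseudocount of 0.5 or 5, no filter, a floor of 5, TMM rescaling, quantile normalisation, a fit of only the groups compared, lane as a covariate, blocks, robust empirical Bayes, array quality weights, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, a 2-fold minimum, and leaving out each library in turn. TMM rescaling changed no value of the fit, since the deposited values already carry such factors. Removal of the rRNA genes, removal of the 2 libraries richest in rRNA reads and removal of the 4 libraries of title numbers 1 to 4 were added after seeing the data, as were list tests without WT GFP-negative replicate 1. List tests blocked by adjacent title numbers and the alternatives of the chromosome 3 ratio were also added then. Sample titles carry numbers, and adjacent numbers (1 and 2, 3 and 4, and so on) belong to a GFP-positive and a GFP-negative library of 1 genotype. The labels do not say that they mark a sort. After group means were removed, log2 values of the 6 adjacent pairs correlated at 0.11 to 0.57, so results of a fit blocked by these pairs are given where they change a call or move a count by over 1.5 times. In the same residuals, 10 of the 12 libraries correlated best with a library of their own run of numbers (1 to 4, 5 to 8 or 13 to 16). Correlations within a run were 0.36 to 0.60 for 1 to 4, 0.04 to 0.52 for 5 to 8 and -0.34 to 0.38 for 13 to 16.

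The procedure was tested on simulated counts with the depth and spread of the libraries. In KO GFP-positive against WT GFP-positive, limma recovered 85% of genes changed 2-fold and 100% of genes changed 4-fold, and called 7 unchanged genes among 192 calls. In the unchanged comparison limma and edgeR called 0 genes and DESeq2 4. DESeq2 recovered 93% of 2-fold changes, with 38 unchanged genes among 231 calls. A planted list was found, and 0 of 40 lists without a change were called. Simulated genes were drawn independently and the unchanged lists at random. The simulation therefore does not test list calls among genes that vary together, as members of the real lists can. Changes were planted only in genes with a mean value of at least 5 over the libraries, so recovery below that was not tested. Libraries were also drawn independently, without the correlation seen within pairs and runs of title numbers. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The reads themselves were not part of the data, so mapping, strand and sequence variants could not be examined.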

Results

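Messenger RNA was profiled in cells sorted by GFP from the brains of Drosophila larvae early in instar 3, where GFP marks cells that express Rfx, a transcription factor known for its control of genes of the primary cilium. Wild-type (WT) and rfx knock-out (KO) brains each gave GFP-positive and GFP-negative cells, with 3 libraries in each of the 4 groups. The table held between 20301256 and 29771321 reads per library. Values are normalised read counts on the CPM scale, given as mean ± SD of 3 libraries. Genes annotated as rRNA took 12.2% of the reads of WT GFP-positive replicate 2 and 2.54% of KO GFP-positive replicate 3, against 0.289% to 0.976% in the other 10 libraries. The first principal component of the tested genes held 66.4% of the variance and separated GFP-positive from GFP-negative libraries.

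The comparison of WT GFP-positive with WT GFP-negative cells asks what distinguishes the cells that express Rfx from the rest of the sorted brain. Rfx itself (FBgn0020379, 3R, 10361760 to 10378068) was 37.9-fold higher in GFP-positive cells, at 2793 ± 217 against 73.7 ± 0.358 (SD, n = 3; adjusted p = 1.56e-11). nompB (FBgn0016919), the fly IFT88 subunit of intraflagellar transport, was 90.0-fold higher at 134 ± 6.10 against 1.49 ± 0.403. Fam92, a partner of Chibby at the ciliary base, stood at 70.8 ± 9.99 against 2.48 ± 0.0876, and Cep290, a component of the ciliary transition zone, at 165 ± 38.5 against 8.89 ± 1.19. In the other direction, the neuroblast transcription factors wor and ase were 75.5-fold and 75.3-fold lower in GFP-positive cells, wor at 5.87 ± 0.228 against 443 ± 33.0 and ase at 4.17 ± 0.627 against 314 ± 32.0. VGlut, the vesicular glutamate transporter, was 7.14-fold higher at 2379 ± 766 against 333 ± 29.95, while Gad1, which makes GABA, was 17.0-fold lower at 21.6 ± 8.98 against 366 ± 75.6.

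Genes of the cilium were among those higher in WT GFP-positive cells. Of 17 intraflagellar transport genes, 11 were higher and 1, rempA, was lower, and 12 and 1 when adjusted over the list alone. Examples are IFT57 at 12.6 ± 2.39 against 0.41 ± 0.268, IFT52 at 23.4 ± 2.98 against 1.70 ± 0.813, and the kinesin-2 motor Klp68D at 246 ± 17.1 against 88.9 ± 2.60. The list was higher than other genes (camera adjusted p = 0.000173), and this held with an estimated correlation (adjusted p = 0.0332). In the BBSome and ciliary base list, 7 of 13 genes were higher and 2, BBS8 and ktub, were lower, but the list as a whole was not called by camera (adjusted p = 0.213). Fry called it as higher (adjusted p = 0.000113). None of 11 axonemal dynein and ciliary motility genes was called by limma, edgeR or DESeq2, with 1 at an unadjusted p under 0.05, and Dhc62B stood at 2.94 ± 1.04 against 6.78 ± 4.43 (list adjusted p = 0.319). Of 7 genes of ciliated mechanosensory neurons, ato, the proneural factor of chordotonal organs, was lower at 0.513 ± 0.125 against 2.64 ± 0.635 and the rest did not pass (list adjusted p = 0.327).

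Progenitor and proliferation genes were lower in WT GFP-positive cells. All but 1 of 29 cell cycle genes were lower, among them polo at 8.995 ± 1.09 against 211 ± 27.5 and CycA at 8.00 ± 0.811 against 219 ± 33.9, and E2f1 was higher (camera adjusted p = 7.48e-28; adjusted p = 0.0401 with an estimated correlation). Of 16 neuroblast and progenitor genes, 13 were lower, such as mira at 5.97 ± 0.323 against 180 ± 29.9 and the receptor Notch (N) at 11.8 ± 1.49 against 166 ± 20.4. The other called members of this list, brat and D, were higher (adjusted p = 6.23e-12; adjusted p = 0.0235 with an estimated correlation). Among 14 genes of newborn neurons and Notch targets, 9 were lower, including E(spl)m7-HLH at 19.4 ± 5.31 against 258 ± 23.1 and E(spl)m8-HLH at 12.02 ± 1.25 against 173 ± 21.5, and pros, scrt and fne were higher (adjusted p = 1.20e-05; adjusted p = 0.0235 with an estimated correlation). Temporal patterning genes, which mark successive neuroblast ages, had 11 of 18 lower and 3 higher, with cas at 16.3 ± 3.90 against 487 ± 75.3 and slp2 at 7.39 ± 1.17 against 163 ± 4.64 (adjusted p = 8.83e-05; adjusted p = 0.0235 with an estimated correlation). Among 61 homeodomain and POU factors, 38 were lower and 13 were higher (adjusted p = 3.26e-10; adjusted p = 0.00247 with an estimated correlation). Lower members included the Iroquois factor mirr, at 3.40 ± 0.907 against 114.6 ± 12.5, and the higher ones included otp, at 542 ± 16.6 against 48.1 ± 0.776, and NK7.1, at 198 ± 18.1 against 55.7 ± 2.03. Adjusted over the list alone, the counts of lower genes were 28 for cell cycle, 13 for neuroblasts, 9 for Notch targets, 11 for temporal patterning and 39 for homeodomain factors.

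Genes of mature neurons were more often higher than lower in WT GFP-positive cells. Pan-neuronal genes had 13 of 19 higher with limma (15 adjusted over the list alone), while edgeR called 8 and DESeq2 11, for instance Appl at 4310 ± 36.7 against 1856 ± 125 and fne at 1686 ± 184 against 746 ± 50.7, while elav stood at 584 ± 73.9 against 659 ± 44.5 and did not pass. Neurotransmitter receptors had 17 of 36 higher and 1 lower, voltage-gated and leak channels 13 of 30 higher, synaptic vesicle and active zone genes 19 of 34 higher and 1 lower (14 called with edgeR and 16 with DESeq2), and cell recognition immunoglobulin genes 22 of 54 higher and 6 lower. TrpA1, a temperature-gated cation channel, stood at 137 ± 44.5 against 4.67 ± 0.970, nAChRalpha2 at 294 ± 5.72 against 109 ± 12.5, and DIP-theta at 198 ± 10.2 against 22.8 ± 1.16. Camera called these lists at adjusted p = 0.00249, 0.00175, 0.00867, 0.00199 and 0.00599, in the order given. All were lost with an estimated correlation, with adjusted p = 0.766, 0.791, 0.766, 0.791 and 0.804. Of 11 immediate early genes, 6 were higher, such as Arc1 at 46.9 ± 14.6 against 9.85 ± 1.11 (adjusted p = 0.0382; adjusted p = 0.766 with an estimated correlation 0.0946 without the 2 libraries richest in rRNA reads and 0.0551 without WT GFP-negative replicate 1).

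Neurotransmitter and neuropeptide genes moved both ways. Of 16 neurotransmitter synthesis and transport genes, 7 were higher, including VGlut, ple and Tdc2, and 5 were lower, including Gad1, Trhn (4.04 ± 2.16 against 54.4 ± 19.0) and Hdc (1.00 ± 0.414 against 12.8 ± 2.06). The list's median log2 change was 0.81 and its mean -0.02, with a test direction of higher (adjusted p = 0.928). Of 37 neuropeptide and neurosecretory genes, 9 were higher and 6 lower (adjusted p = 0.928). Ms, which encodes myosuppressin, stood at 250 ± 185 against 1.51 ± 0.274, AstC (allatostatin C) at 228 ± 191 against 13.0 ± 2.13, and CNMa at 41.4 ± 39.97 against 1.52 ± 0.165. These SDs reflect replicate 2, in which Ms reached 463, AstC 443 and CNMa 86.3. Across the 37 genes, the median deviation from the group mean (log2) was 0.74, 0.30, 0.57 and 0.84 in replicate 2 of WT GFP-positive, WT GFP-negative, KO GFP-positive and KO GFP-negative cells. In the other 8 libraries it lay between -0.71 and 0.00. Without WT GFP-positive replicate 2 the ratio of group means went from 165 to 94.6 for Ms, from 17.5 to 9.27 for AstC and from 27.2 to 12.5 for CNMa. In the same 4 libraries the deviation was 0.64, 0.31, 0.65 and 0.78 for neurotransmitter synthesis and transport and 0.39, 0.10, 0.36 and 0.26 for pan-neuronal genes.

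Markers of other cell types gave mixed counts. Of 20 glial genes, 8 were lower, among them Eaat1 at 14.1 ± 2.08 against 213 ± 34.7 and gcm at 1.34 ± 0.520 against 47.4 ± 4.34, and 6 were higher (adjusted p = 0.0325; adjusted p = 0.766 with an estimated correlation; 0.0789 in a fit blocked by adjacent title numbers). Optic lobe and eye disc genes had 7 of 20 higher, including eya (535 ± 13.8 against 95.9 ± 15.8) and so (111 ± 7.57 against 12.05 ± 3.09), and 6 lower, with a median of -0.06, a mean of 0.12 and a test direction of lower (adjusted p = 0.722). Mushroom body genes had 6 of 14 higher and 2 lower (adjusted p = 0.633), and axon guidance genes 17 of 36 higher and 9 lower (adjusted p = 0.382). Hemocyte markers had 4 of 9 higher, with the collagen Col4a1 at 87.3 ± 42.6 against 13.0 ± 6.89 (adjusted p = 0.268). Of 10 muscle genes, 3 were lower (adjusted p = 0.0137; 0.766 with an estimated correlation and 0.11 without WT GFP-negative replicate 1), as were 4 of 7 genes of trachea and epidermis (adjusted p = 0.00738; 0.527 with an estimated correlation), led by the POU factor vvl, which is also a member of the homeodomain list. Ecdysone response genes had 6 of 16 higher and 3 lower (median 0.19, mean -0.03, adjusted p = 0.928), and heat shock and cell stress genes 4 of 25 higher and 2 lower (median 0.00, mean 0.13, test direction lower, adjusted p = 0.928). Cytosolic ribosomal protein genes had 1 of 79 higher and 2 lower with limma, against 6 called with edgeR and 27 with DESeq2, with a median of -0.29 (adjusted p = 0.000173; 0.804 with an estimated correlation). Fry parted from camera on several of these lists. It called mushroom body, axon guidance and hemocyte genes as higher (fry adjusted p = 0.0455, 0.0125 and 0.0125). It did not call muscle or ribosomal proteins (0.0663 and 0.384). No gene passed among 5 of the fat body (adjusted p = 0.556) or 3 of antimicrobial response (adjusted p = 0.928) by limma, edgeR or DESeq2, with 0 and 1 at an unadjusted p under 0.05. The dosage compensation RNAs roX1 and roX2, too few for a list test, stood at 2459 and 324 in WT GFP-positive and at 2330 and 297 in WT GFP-negative cells.

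Other genes with large differences in WT belong to no list discussed above. CG15082 (log2 4.91), the chitinase gene Cht6 (4.01), CG4476 (3.86) and CG18599 (3.75) were higher in GFP-positive cells. tap (-5.45), lncRNA:CR30009 (-5.42), spdo, a regulator of Notch in asymmetric division (-5.38), CG12239 (-5.25), lncRNA:CR44832 (-5.14), CG11294 (-5.06), CG5235 (-4.95) and msb1l (-4.72) were lower. The ratio of group means went from 50.2 to 27.4 for CG15082 without WT GFP-positive replicate 2, and from 41.3 to 77.7 for CG12239 without replicate 1.

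Of 9912 genes tested between WT GFP-positive and WT GFP-negative cells, 2550 were higher and 1215 lower, and 1241 of these 3765 changed at least 2-fold. The share that was higher, 67.7% with limma, was 57.1% with quantile normalisation, 55.6% with edgeR and 51.9% with DESeq2. The median log2 change of all tested genes was 0.09 with limma, -0.03 with edgeR and -0.06 with DESeq2. Of 29 lists, 16 were called, 7 as higher and 9 as lower, and 6 held with an estimated correlation.

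**Figure D1:**
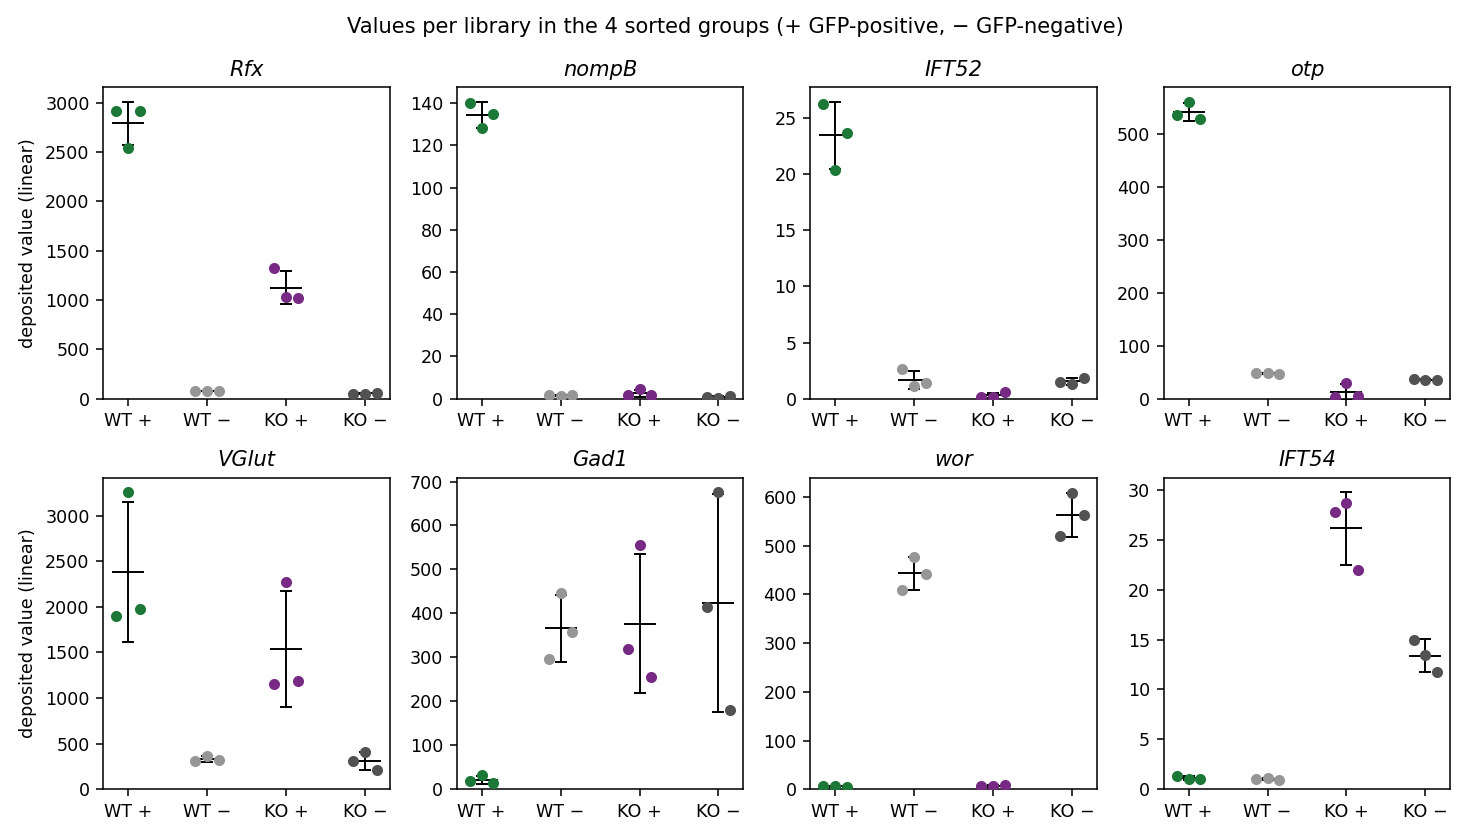
Normalised read counts (linear axis, CPM scale) of 8 genes in the 12 libraries. Points are libraries, bars are the mean and SD of 3 libraries, and + and − stand for GFP-positive and GFP-negative cells; nompB falls from 134 in WT to 2.68 in KO GFP-positive cells, while IFT54 rises from 1.14 to 26.1.

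**Figure D2:**
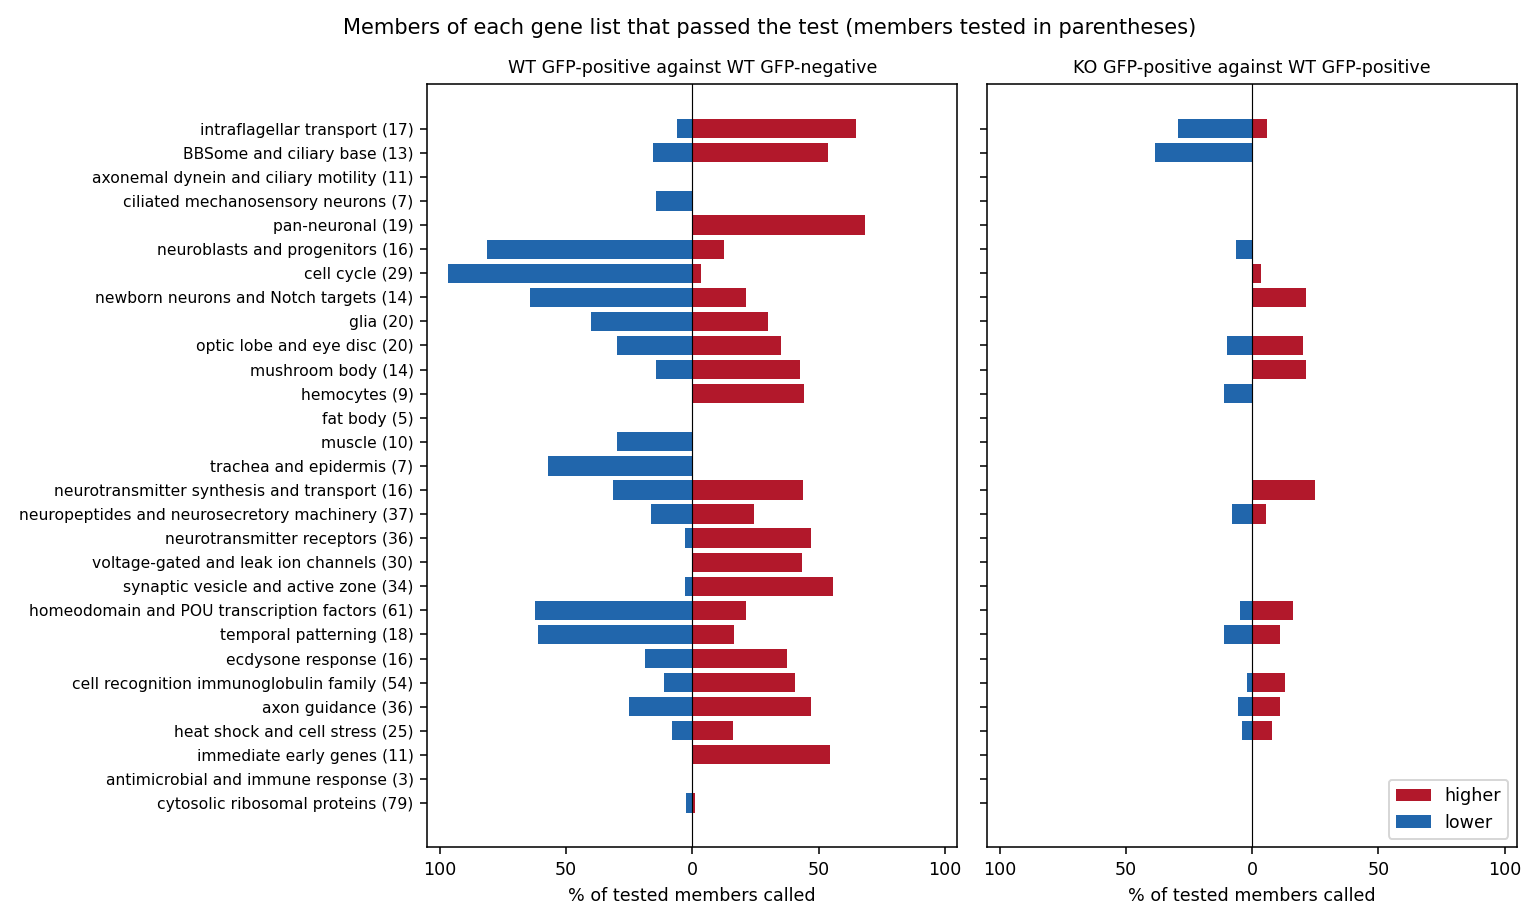
Share of the tested members of each gene list that was called higher (right) or lower (left) with limma, in percent, for the GFP comparison in WT cells and the knock-out comparison in GFP-positive cells. In the GFP comparison 28 of 29 cell cycle genes were lower and 11 of 17 intraflagellar transport genes higher, and in the knock-out comparison 5 of 17 intraflagellar transport genes were lower.

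The comparison of KO with WT GFP-positive cells asks what the knock-out changes in the cells that GFP marks. Rfx fell from 2793 ± 217 to 1126 ± 170 (SD, n = 3), a log2 change of -1.32 ± 0.11 (SE; adjusted p = 1.03e-05), so transcripts of the gene were still counted in KO cells. nompB (2L, 21578292 to 21589423) fell 50.2-fold, from 134 ± 6.10 to 2.68 ± 1.65 (adjusted p = 1.71e-07), and IFT52 (FBgn0031829; 2L, 6555717 to 6557502), another intraflagellar transport subunit, fell from 23.4 ± 2.98 to 0.286 ± 0.263. The homeodomain gene otp (FBgn0015524; 2R, 20883625 to 20903414) fell 43.1-fold, from 542 ± 16.6 to 12.6 ± 14.9. Without KO GFP-positive replicate 2 the falls were 135-fold for otp and 78.1-fold for nompB. Without replicate 3 that of IFT52 went from 82.1-fold to 174-fold. Gad1 (FBgn0004516; 3L, 4074077 to 4088744) rose 17.4-fold, from 21.6 ± 8.98 to 377 ± 158 (adjusted p = 9.07e-05), and stood at 366 ± 75.6 in WT and 423 ± 248 in KO GFP-negative cells. IFT54 (FBgn0038221; 3R, 14302428 to 14304458) rose from 1.14 ± 0.193 to 26.1 ± 3.63.

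Ciliary genes fell in KO GFP-positive cells as groups. Of 17 intraflagellar transport genes, nompB, IFT52, IFT57 (12.6 ± 2.39 to 1.72 ± 0.287), Oseg5 (7.52 ± 0.512 to 0.651 ± 0.499) and IFT43 fell, IFT54 rose and 11 did not pass, with 6 falling and 3 rising when adjusted over the list alone. Camera gave an adjusted p of 1.49e-05 for the fall of the list, and 0.0306 with an estimated correlation. Of 13 genes of the BBSome and ciliary base, BBS1, B9d1, dila (28.9 ± 5.34 to 6.71 ± 2.60), Root (33.5 ± 6.76 to 10.2 ± 2.55) and dnd, the fly Arl3 (8.38 ± 0.894 to 0.259 ± 0.320; 32.3-fold, or 111-fold without KO GFP-positive replicate 3), fell, and 7 fell adjusted over the list alone (adjusted p = 5.50e-09; 0.0147 with an estimated correlation). Cep290 did not pass, at 165 ± 38.5 in WT and 112 ± 13.7 in KO. Outside these lists, Fam92 fell from 70.8 ± 9.99 to 7.12 ± 1.72, hmw, known for flagellar and ciliary motility, from 20.6 ± 2.82 to 0.505 ± 0.203, and nmdyn-D7, the fly NME7, from 21.9 ± 3.41 to 1.81 ± 0.353. Axonemal dynein genes (0 of 11), ciliated mechanosensory genes (0 of 7) and pan-neuronal genes (0 of 19) had no call by limma or edgeR, with 1, 2 and 1 at an unadjusted p under 0.05, and DESeq2 called 1 mechanosensory gene (list adjusted p = 0.11, 0.517 and 0.204). The axonemal dynein list was called as lower with lane as a covariate, without title numbers 1 to 4 and without the 2 libraries richest in rRNA reads (adjusted p = 0.00577, 0.00772 and 0.00327), and the pan-neuronal list as higher (0.0263, 0.0457 and 0.00861). In the main fit, camera with an estimated correlation gave both lists an adjusted p of 0.946.

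Genes of neuronal identity moved in both directions in KO GFP-positive cells. Among 61 homeodomain and POU factors, 10 rose, including C15 (0.664 ± 0.242 to 9.96 ± 1.33), ara (1.28 ± 0.383 to 13.4 ± 3.20) and zfh1 (20.8 ± 3.85 to 68.5 ± 9.29), and otp, Dr and oc fell. The list was not called by camera (adjusted p = 0.204, median -0.02, mean 0.09), and the counts adjusted over the list alone were 13 and 3. Fry called it as higher (adjusted p = 0.00226). Of 16 neurotransmitter synthesis and transport genes, 4 rose: Gad1, Hdc, which makes histamine (1.00 ± 0.414 to 7.97 ± 1.14), Tdc2, which makes tyramine (14.9 ± 4.82 to 104.7 ± 68.2), and the serotonin transporter SerT (adjusted p = 0.016 for the list; adjusted p = 0.946 with an estimated correlation). Replicate 2 stood 0.64 (WT) and 0.65 (KO) above the group mean on this list (median log2). VGlut did not pass, at 2379 ± 766 in WT and 1539 ± 636 in KO. Of 37 neuropeptide and neurosecretory genes, Tk and dimm rose and 3 fell (adjusted p = 0.866, median 0.06, mean -0.01): Ms from 250 ± 185 to 14.0 ± 22.1, CCHa1 from 31.6 ± 15.9 to 3.93 ± 3.91, and CNMa from 41.4 ± 39.97 to 4.85 ± 2.93. In KO GFP-positive replicate 2 Ms stood at 39.6, against 1.46 and 1.06 in the other 2 libraries. Without it the fall of Ms went from 17.8-fold to 198-fold and that of CCHa1 from 8.06-fold to 18.9-fold. Without WT GFP-positive replicate 2 that of Ms was 10.2-fold. CNMa stood at 86.3 in WT GFP-positive replicate 2, against 9.55 in replicate 1 and 28.4 in replicate 3. The fall of Ms had an adjusted p of 0.00411, but 0.0617 with edgeR, 0.0709 with only these groups in the fit and 0.0535 without the 2 libraries richest in rRNA reads (log2 -5.17 to -3.84). That of CCHa1 had 0.0123, but 0.133 without those 2 libraries, 0.0736 with edgeR, 0.0662 without KO GFP-positive replicate 1 and 0.0617 without replicate 3.

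Smaller shifts were seen in lists of developmental and recognition genes. Of 14 newborn neuron and Notch target genes, Hey (log2 change 0.82), E(spl)m7-HLH (19.4 ± 5.31 to 45.0 ± 1.49) and E(spl)m8-HLH (12.02 ± 1.25 to 23.7 ± 2.00) rose (adjusted p = 0.000967; 0.0705 with an estimated correlation). Of 14 mushroom body genes, ey (63.5 ± 0.860 to 121 ± 9.74), dac (132 ± 13.0 to 249 ± 11.3) and Fas2 (379 ± 28.5 to 597 ± 29.8) rose (adjusted p = 0.00281; 0.478 with an estimated correlation). Cell recognition immunoglobulin genes had 7 of 54 higher, among them DIP-beta (33.7 ± 5.04 to 107 ± 37.5), and DIP-theta fell from 198 ± 10.2 to 97.7 ± 12.3 (adjusted p = 0.000868; 0.946 with an estimated correlation). Of 29 cell cycle genes only Klp61F rose, from 5.14 ± 1.22 to 13.7 ± 2.34 (list adjusted p = 0.016; 0.946 with an estimated correlation). Without the 2 libraries richest in rRNA reads the cell cycle list was not called and its direction was lower (adjusted p = 0.953). Axon guidance genes had 4 of 36 higher (comm, caps, trn and Ten-m) and 2 lower (Drl-2 and NetB), optic lobe genes 4 of 20 higher (among them tll) and 2, lz and oc, lower, and temporal patterning genes 2 of 18 higher and 2, erm and opa, lower (adjusted p = 0.25, 0.223 and 0.181). Of 16 neuroblast genes only erm fell (median 0.07, mean -0.01, test direction lower, adjusted p = 0.871; 0.0344 without the libraries richest in rRNA reads). In the main fit camera gave this list 0.946 with an estimated correlation, and 2 members rose and 1 fell when adjusted over the list alone. In all, 7 of 29 lists were called by camera, 5 as higher and 2 as lower, and 2 held with an estimated correlation. Fry also called optic lobe genes as higher (adjusted p = 0.0177). It did not call the cell cycle, neurotransmitter synthesis and transport, or cell recognition lists (0.642, 0.566 and 0.651).

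Several large changes in KO GFP-positive cells were also called between KO and WT GFP-negative cells. mthl8, a receptor of the methuselah family, rose from 0.475 ± 0.646 to 145 ± 11.02, Hsc70-2 from 0.46 ± 0.284 to 54.2 ± 7.12, and w, the eye colour transporter gene often used to mark transgenes, from 81.5 ± 20.9 to 2816 ± 554. CG31157 rose from 0.349 ± 0.121 to 21.7 ± 2.16, CG42556 from 0.952 ± 0.222 to 15.6 ± 1.06, CG42846 from 0.254 ± 0.116 to 8.47 ± 2.24, and ry from 1.82 ± 0.576 to 24.7 ± 15.7. CG11307 fell from 85.6 ± 1.91 to 1.62 ± 1.29, and Hsp70Ba, which has near-identical copies, from 27.6 ± 6.65 to 2.05 ± 1.10. The rise of mthl8 went from 305-fold to 1418-fold without WT GFP-positive replicate 1, and that of ry from 13.6-fold to 8.73-fold without KO GFP-positive replicate 3. The fall of CG11307 went from 52.95-fold to 97.6-fold without KO GFP-positive replicate 2. Other large changes were not called in GFP-negative cells. CG14989, whose span overlaps that of Gad1 on the other strand, rose from 48.2 ± 15.0 to 1209 ± 321 and Jhbp2 from 1.62 ± 0.130 to 24.9 ± 14.5, while the transporter Oatp26F fell from 142 ± 10.54 to 4.68 ± 1.44, and the interaction was called for all 3. lncRNA:CR44832 rose from 3.85 ± 2.05 to 69.2 ± 64.01 (interaction adjusted p = 0.111), but its adjusted p was 0.0649 without the 2 libraries richest in rRNA reads. Its rise was 8.49-fold without KO GFP-positive replicate 2.

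Between KO and WT GFP-positive cells, limma called 304 of 9912 genes, 173 higher and 131 lower, and 178 changed at least 2-fold. The count was 302 with edgeR and 505 with DESeq2, 475 in a fit blocked by runs of title numbers, 186 in a fit of these 2 groups alone and 199 without WT GFP-positive replicate 1. With lane as a covariate it was 385. Among genes named for this comparison, at least 5% of the exon bases are shared with a gene on the other strand in dnd (25.8%, CG6678), Klp61F (10.95%, galene), BBS1 (9.96%, Acbp4, which was not tested), otp (9.53%, asRNA:CR43160, which was not tested), Oatp26F (9.18%, CG34345), IFT43 (7.72%, CG6153) and nmdyn-D7 (6.32%, CG9444), and the protocol does not separate the strands.

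**Figure D3:**
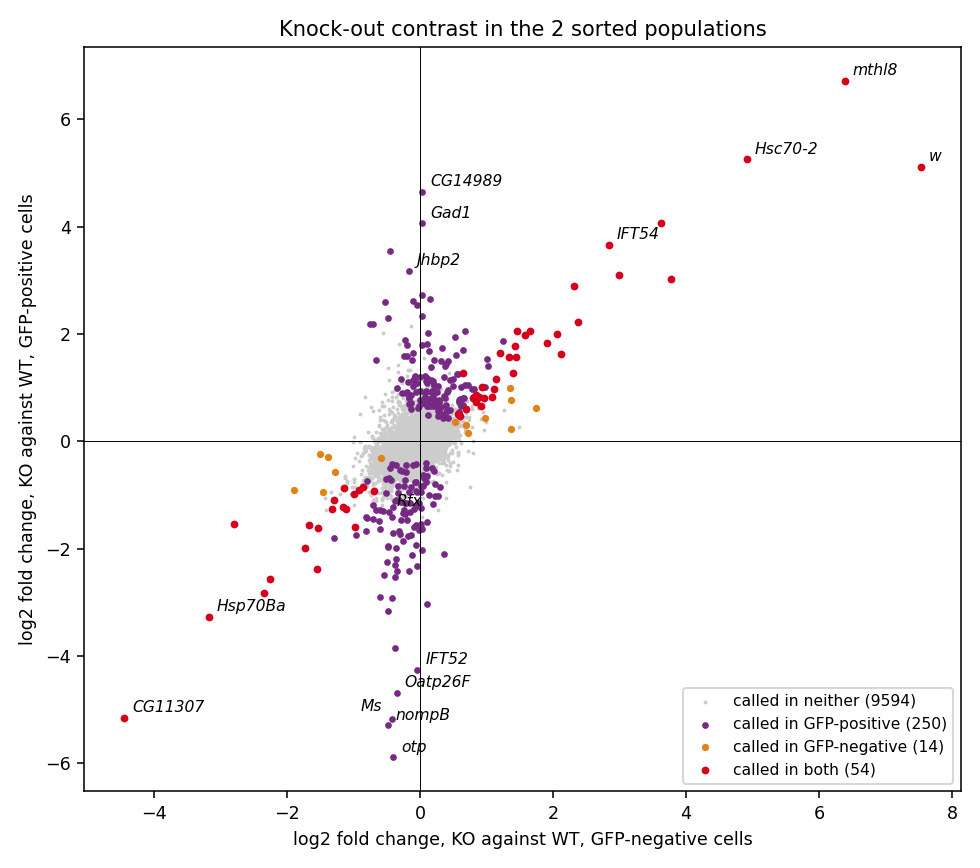
Log2 fold change of KO against WT in GFP-negative cells (x axis) and GFP-positive cells (y axis) for 9912 genes, each a point, coloured by the comparison in which limma called it. The 54 genes called in both, such as mthl8 and CG11307, changed in the same direction, while nompB, otp and Gad1 change in GFP-positive cells.

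The comparison of KO with WT GFP-negative cells shows how the genotypes differ outside the GFP-positive cells. w rose 205-fold, from 8.81 ± 5.65 to 1803 ± 981 (SD, n = 3), mthl8 from 0.252 ± 0.264 to 103 ± 10.47, Hsc70-2 from 0.969 ± 0.779 to 55.8 ± 3.52, and ry, which encodes xanthine dehydrogenase, from 1.49 ± 0.841 to 36.9 ± 24.8. CG11307 fell 33.6-fold, from 53.1 ± 7.12 to 1.58 ± 1.01, and Hsp70Ba, the glutathione transferase GstD3 (10.96 ± 4.25 to 0.634 ± 0.193) and the ionotropic receptor Ir76a (24.8 ± 3.39 to 4.24 ± 1.72) also fell. Ir76a shares 14.1% of its exon bases with CG14102. Without WT GFP-negative replicate 1 the rise of w was 323-fold, that of mthl8 went from 409-fold to 1039-fold and that of Hsc70-2 from 57.5-fold to 107-fold. The fall of CG11307 was 52.1-fold without KO GFP-negative replicate 2. Without replicate 3 the rise of ry went from 24.7-fold to 15.6-fold and the fall of Hsp70Ba from 12.2-fold to 18.7-fold. Rfx stood at 73.7 ± 0.358 and 53.05 ± 1.30, a log2 change of -0.47 that did not pass with limma (adjusted p = 0.0948) but passed with DESeq2 (0.000638), with array quality weights (0.0023) and in a fit blocked by runs of title numbers (0.0436). IFT54 was the only ciliary list gene called, at 1.01 ± 0.0863 in WT and 13.4 ± 1.62 in KO. Camera called muscle, voltage-gated channels and ribosomal proteins as lower (adjusted p = 0.0116, 0.0116 and 0.00292), with 0 members called by limma, edgeR or DESeq2 and 1, 1 and 0 at an unadjusted p under 0.05; the adjusted p of each was 0.838 with an estimated correlation, and that of ribosomal proteins 0.647 with lane as a covariate and 0.0566 without title numbers 1 to 4. WT GFP-negative replicate 1 stood above its group mean by 0.66 for muscle, 0.92 for fat body and 0.50 for hemocyte markers (median log2), and without it muscle and the channels were not called (adjusted p = 0.693 and 0.913). Fry gave each of the lists that camera called here an adjusted p of 0.897. In all, limma called 43 genes higher and 25 lower, 68 together, against 68 with edgeR and 153 with DESeq2.

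The knock-out comparisons in the 2 sorted populations share no library. Their log2 fold changes correlated across 9912 genes at r = 0.528 (rho = 0.454), and 54 genes were called in both, 35 higher, 19 lower and 0 in opposite directions with limma. Libraries with adjacent title numbers, which lie across the 2 comparisons, correlate at 0.11 to 0.57 after group means are removed, so the errors of the comparisons are not independent. When the 6 adjacent pairs were split in the 9 other ways, r lay between 0.136 and 0.700 and was at least as large in 2 of them, so r alone does not mark a shared difference between the genotypes. The highest count of genes called in both was 0 by limma in those splits. Each of those splits mixes the genotypes on both sides, so genotype differences enter the spread within groups and lower the counts. Part of the genotype difference also stays in their r. The splits therefore do not show what r or the count would be without a genotype difference. Of the 66 placed genes called in GFP-negative cells, 48 lie on chromosome 3, which carries Rfx, or 72.7% against 44.1% of tested genes (odds ratio 3.40, 95% interval 1.94 to 6.23, exact p = 4.24e-06). On the arms, 3R held 27 and 3L held 21 (odds ratios 2.16 and 1.91, exact adjusted p = 0.0124 and 0.0441), while 2R held 3 (odds ratio 0.190, adjusted p = 0.00392) and Y held 1, CR41504, of its 4 tested genes (odds ratio 49.2, interval 0.928 to 622, adjusted p = 0.0471). Of the 300 placed genes called in GFP-positive cells, 159 lie on chromosome 3 (odds ratio 1.44, exact p = 0.00174) and 39 on 2R (odds ratio 0.593, exact adjusted p = 0.0137), and of the 248 called there alone, 122 (odds ratio 1.23, exact p = 0.106). ry, Hsc70-2 and CG31157 are neighbours on 3R. Called genes are thus not all independent, and the exact p and intervals may be too narrow.

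**Figure D4:**
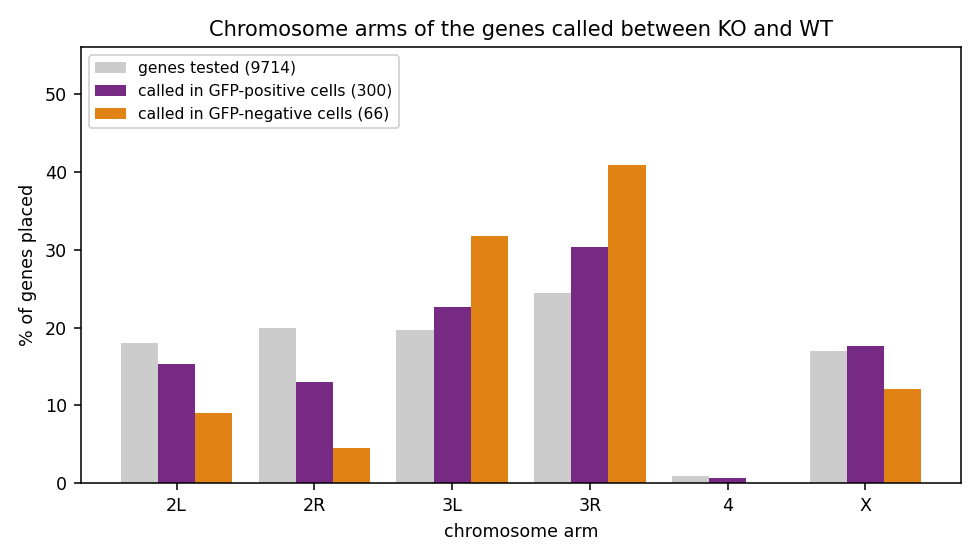
Share of genes on each chromosome arm other than Y, in percent of the genes with a position, for all tested genes (9714), genes called between KO and WT in GFP-positive cells (300) and those called in GFP-negative cells (66). Arm 3R holds 24.4% of tested genes, 30.3% of the GFP-positive calls and 40.9% of the GFP-negative calls.

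The GFP comparison repeated in KO brains asks whether the sorted populations stay distinct in KO brains, where Rfx transcripts were still counted. Rfx was 21.2-fold higher in KO GFP-positive cells, at 1126 ± 170 against 53.05 ± 1.30 (SD, n = 3), and TrpA1 20.5-fold higher, at 90.9 ± 14.6 against 4.44 ± 1.12. Tdc2 stood at 104.7 ± 68.2 against 2.91 ± 2.46 and CG4476 at 92.9 ± 87.5 against 2.17 ± 0.722. The ratio for Tdc2, 36.0, was 22.5 without KO GFP-positive replicate 2 and 65.7 without KO GFP-negative replicate 2, and that for CG4476, 42.9, was 22.1 without KO GFP-positive replicate 1. wor was lower at 7.33 ± 1.66 against 564 ± 45.1, ase at 6.39 ± 1.16 against 399 ± 41.8, tap at 9.58 ± 3.70 against 402 ± 68.6, and the homeobox gene CG11294 at 2.03 ± 0.217 against 121 ± 21.2. Again 28 of 29 cell cycle genes and 13 of 16 neuroblast genes were lower (adjusted p = 0.0479 and 0.0262 with an estimated correlation). Intraflagellar transport genes had 8 of 17 higher and 2, IFT52 and IFT43, lower, and the list was not called by camera (adjusted p = 0.0564). Fry called it as higher (adjusted p = 0.000104). Among lists uncalled here, 2 were called in a fit blocked by adjacent title numbers, muscle (0.0564 to 0.0196) and neurotransmitter synthesis and transport (0.0874 to 0.0161). Without the block, camera with an estimated correlation gave these 2 lists an adjusted p of 0.680 and 0.736. Of 29 lists 14 were called, and 5 held with an estimated correlation. limma called 2341 genes higher and 1274 lower, 3615 together, of which 1325 changed at least 2-fold. The share that was higher was 64.8% with limma, 55.0% with quantile normalisation, 52.9% with edgeR and 53.7% with DESeq2. Log2 fold changes correlated with those of the WT comparison at r = 0.912 (rho = 0.891) across genes, and 2931 genes were called in both, 9 of them in opposite directions.

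The interaction tests whether the knock-out difference itself differs between GFP-positive and GFP-negative cells. Among called genes, otp, nompB, Oatp26F and IFT52 had negative interactions of log2 -5.48 ± 0.71, -4.80 ± 0.38, -4.34 ± 0.31 and -4.22 ± 0.33 (SE; adjusted p = 0.00238, 6.41e-05, 5.96e-05 and 6.41e-05). CG14989, Gad1, Jhbp2 and Hdc had positive ones of 4.61 ± 0.38, 4.02 ± 0.61, 3.34 ± 0.43 and 2.89 ± 0.47 (adjusted p = 8.14e-05, 0.00835, 0.00238 and 0.0129). Hdc did not pass without KO GFP-negative replicate 1 (adjusted p = 0.0508) or without the 2 libraries richest in rRNA reads (0.0633). nompB, IFT52 and dnd stood at only 1.49, 1.70 and 0.954 in WT GFP-negative cells, near the 1 added before the log. That compresses a fall there and favours a negative interaction. Rfx had an interaction of -0.85 ± 0.15 (adjusted p = 0.0236), which did not pass with quantile normalisation (adjusted p = 0.212), without title numbers 1 to 4 (0.208), without rRNA genes (0.0696) or when any of 10 of the 12 libraries was left out (0.0523 to 0.0837). Intraflagellar transport (nompB, IFT57, IFT52 and IFT43 called, 4 of 17 lower) and the BBSome and ciliary base (B9d1, Root and dnd, 3 of 13 lower) were called as lower, with adjusted p = 1.53e-05 and 2.29e-08, and 0.0244 and 0.0186 with an estimated correlation. Of the 17 transport genes edgeR called 3 and DESeq2 4, and of the 13 BBSome and ciliary base genes edgeR called 1 and DESeq2 3. Newborn neuron and Notch target genes were called as higher (adjusted p = 1.74e-05; 0.0244 with an estimated correlation), with 0 of 14 called by limma, 4 at an unadjusted p under 0.05, 1 by edgeR and 3 by DESeq2. Of 29 lists 13 were called, 11 as higher and 2 as lower, and 3 held with an estimated correlation. limma called 28 genes higher and 27 lower, 55 together, against 53 with edgeR and 116 with DESeq2. A fit blocked by adjacent title numbers called 108, with all 55 among them, and neuropeptides as a list (0.131 to 0.0173), and without KO GFP-negative replicate 1 the count was 34.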

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

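The tests on GFP-negative cells in the sort, on a held-out library and on the mix of neurons were chosen only after the results they examine were seen. Counting genotype calls by chromosome arm was planned, while the explanations set against the chromosome 3 ratio were written afterwards. The knock-out difference differed between GFP-positive and GFP-negative cells, by the interaction test of limma, for 55 genes, among them 13 of the genes named for the size of their fold change (log2, with the change in GFP-positive and then in GFP-negative cells). It was 4.61 for CG14989 (4.64 and 0.03), 4.02 for Gad1 (4.06 and 0.03), 3.34 for Jhbp2 (3.17 and -0.18) and 2.89 for Hdc (2.18 and -0.71). It was -0.85 for Rfx (-1.32 and -0.47), -2.50 for dnd (-2.92 and -0.42), -2.68 for Fam92 (-3.16 and -0.48) and -3.13 for nmdyn-D7 (-3.02 and 0.11). It was -3.47 for hmw (-3.85 and -0.37), -4.22 for IFT52 (-4.26 and -0.04), -4.34 for Oatp26F (-4.69 and -0.35), -4.80 for nompB (-5.29 and -0.49) and -5.48 for otp (-5.89 and -0.41). Adjusted p ran from 5.96e-05 for Oatp26F to 0.0236 for Rfx. In WT GFP-negative cells nompB, IFT52, hmw, dnd and Fam92 stood at 1.49, 1.70, 1.12, 0.954 and 2.48, near the 1 added before the log. A fall there is compressed on this scale, which favours a negative interaction for these genes.

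Other splits of the same libraries were run for each count of called genes. For each comparison of 2 groups, 1 of the 10 splits, the real one, gave a count as large. The real counts were 304 (KO against WT, GFP-positive), 3765 (GFP, WT), 68 (KO against WT, GFP-negative) and 3615 (GFP, KO), and the highest other counts were 1, 0, 0 and 0 by limma. With 10 splits no share under 0.05 can be reached. Every other split also mixes the 2 groups, so differences between them enter the spread and low counts follow from the mixing. In the GFP comparisons, 4 of the 10 splits part every adjacent pair of title numbers. For the interaction, 10 of 100 relabellings drawn from 200 gave at least the 55 genes of the real labels, so chance is not excluded by that share. Of these 10, 9 keep the labels of the GFP-positive libraries, and so the knock-out difference there, and the share therefore says little for or against chance. The highest other count was 1409, in a relabelling that sets title numbers 1 to 4 against 5 to 8 and divides 13 to 16, so differences between those 2 runs enter that count. The count was 101 in a fit blocked by run and 108 in a fit blocked by adjacent title numbers. Among the 7 drawn that keep adjacent title numbers together the highest other count was 0.

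Of genes at least 4-fold lower in WT GFP-positive than GFP-negative cells, 29 of 318 rose and 1 fell with the knock-out in GFP-positive cells (173 of all 9912 tested genes rose), but they were chosen on the WT libraries that also serve as its control, which favours rises. With all libraries, the 318 genes had a median log2 change of 0.15. Chosen on 2 of the WT GFP-positive libraries and compared with the held-out one, such genes had a median of 0.06 to 0.25. The held-out library itself stood at -0.16 to 0.11 against the other 2. If GFP-negative cells in the KO GFP-positive sort were the source, the 29 genes would imply a median share of 17.5% (quartiles 8.09 to 54.3). Progenitor and cell cycle genes, which GFP-negative cells as a whole would bring, implied 1.07% (35 genes, quartiles 0.192 to 2.67). The highest of these was 8.52, for Klp61F, which is in both sets. The 29 genes were chosen for their rise and the 35 were not, which favours a larger share in the 29. Progenitor genes also do not speak on GFP-negative neurons alone. At most, the values argue against GFP-negative cells in their sorted proportions, for the 18 genes past that highest share. Another mix of neurons among the GFP-positive cells stays open. VGAT, the vesicular GABA transporter, stood at 104 ± 12.6 in WT and 144 ± 17.1 in KO. Its log2 change of 0.46 did not pass with limma (adjusted p = 0.212). In WT, VGAT did not follow Gad1, at 95.4 to 119 in GFP-positive and 67.6 to 84.0 in GFP-negative libraries. It therefore leaves another mix undecided. A change in these genes within KO GFP-positive cells may also account for the pattern, was not tested, and cannot be told apart from another mix.

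Genes called between KO and WT in GFP-negative cells were concentrated on chromosome 3, which carries Rfx. The odds ratio of 3.40 (interval 1.94 to 6.23; 2.13 to 10.6 across the alternatives) is the observation itself, found on the same data, so it decides between no explanations. Variants linked to the mutated chromosome may account for part of the calls, and so may the knock-out of Rfx if its targets lie there. These cannot be told apart, and 18 of the 66 placed genes lie elsewhere. The rise of w, which lies on X and is often used to mark transgenes, may come from strain construction, which was not tested. The reads that would show variants were not available.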

How the results depend on the processing

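Removing rRNA genes, the 2 libraries richest in rRNA reads or the 4 libraries of title numbers 1 to 4, and testing lists without WT GFP-negative replicate 1, was chosen after seeing the data. So were list tests blocked by adjacent title numbers and the alternatives of the chromosome 3 ratio. Across the counts, correlations, list tests, Rfx changes and chromosome 3 ratio, 225 alternatives kept their side of the test or, for counts and correlations, stayed within 1.5 times or the spread, 30 moved and 0 reversed. Counts of genes and lists were compared by number, not by which were called. With quantile normalisation 2854 of 3765 (GFP, WT), 2894 of 3615 (GFP, KO) and 275 of 304 genes (KO against WT, GFP-positive) were called again. With edgeR these were 3134, 3133 and 275. The chromosome 3 ratio (3.40) kept its side but ran from 2.13 with array weights to 10.6 without title numbers 1 to 4. The count of genes in KO against WT GFP-positive cells (304) was 186 with only those groups in the fit, 475 with a run block, 544 with array weights, 505 with DESeq2, 178 with a 2-fold minimum, and 199 (without WT GFP-positive replicate 1) to 256 with 1 library left out. The GFP counts were 1241 (WT) and 1325 (KO) with a 2-fold minimum, and 2957 to 3859 and 2679 to 3859 with 1 library left out. KO against WT in GFP-negative cells (68) gave 497 with array weights, 153 with DESeq2, 39 without title numbers 1 to 4, and 49 to 70 with 1 library left out. The interaction (55) gave 101 with a run block, 108 with adjacent title numbers as blocks, 139 with array weights, 116 with DESeq2, 32 without title numbers 1 to 4, and 34 (without KO GFP-negative replicate 1) to 51. The correlation of the GFP comparisons was 0.879 without the rRNA-rich libraries, 0.880 without title numbers 1 to 4, and 0.887 to 0.917 with 1 library left out, and that of the knock-out comparisons 0.405 to 0.570. With an estimated correlation the called lists went from 7 to 2 (KO against WT, GFP-positive), 16 to 6 (GFP, WT), 3 to 0 (KO against WT, GFP-negative, camera), 14 to 5 (GFP, KO) and 13 to 3 (interaction). In KO against WT GFP-positive cells, 13 lists were called with lane as a covariate, 11 without title numbers 1 to 4 and 12 without the rRNA-rich libraries; in GFP-negative cells, 11 and 5 without those libraries and 1 without WT GFP-negative replicate 1. A 2-fold minimum keeps fewer genes by construction, and leaving out libraries tests fewer samples; for the other alternatives the cause was not tested. Array weights gave a convergence warning, and TMM rescaling changed nothing by construction. With 1 library left out, the Rfx change was -1.44 to -1.25 with the knock-out and 5.19 to 5.29 with GFP, and the chromosome 3 ratio 3.75 to 5.69. Of 1689 alternatives for 73 named gene results, 1663 gave the same call, 23 a weaker and 3 a stronger one, and 0 reversed. The weaker ones concern lncRNA:CR44832, Ms, CCHa1, Hdc and Rfx. Apart from Rfx, these genes were chosen for large changes without overlap in the same libraries, which favours the same call. TMM rescaling is counted among the alternatives.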

Other observations

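The genes in this part were chosen after their values were seen, and the differences are given as values. They include 9 genes of the circadian clock, which were not tested as a list, in a comparison where 3765 of 9912 genes were called. In WT, tim stood at 69.8 ± 6.07 in GFP-positive and 8.996 ± 2.50 in GFP-negative cells (adjusted p = 3.60e-07), and Clk at 26.3 ± 2.50 and 3.52 ± 1.46 (adjusted p = 3.04e-06). cyc, Pdp1, cwo, cry and vri were also higher, with log2 changes of 0.82, 0.91, 0.96, 0.96 and 0.42. per stood at 25.3 ± 7.91 and 22.8 ± 1.29 (adjusted p = 0.663), and the neuropeptide gene Pdf was lower, with a log2 change of -2.02 (adjusted p = 0.0132). In KO GFP-positive cells Clk was at 7.26 ± 1.46, a log2 change of -1.74 (adjusted p = 0.00089), and vri changed by -0.71 (adjusted p = 0.0238), while tim stood at 84.0 ± 8.84 and did not pass. The interaction was not called for any of these 9 genes by limma (adjusted p = 0.9998 each).

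Genes at least 4-fold higher in WT GFP-positive than GFP-negative cells were chosen on 2 of the 3 WT GFP-positive libraries, and KO GFP-positive cells were compared with the held-out one. The 66 to 99 such genes had median changes of -1.16 to -0.12 (log2) in KO, and single genes were not tested against 1 library. The held-out library itself stood at -0.33 to 0.15 against the other 2, so the size of the KO median depends on the library held out.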
